A study of Mus musculus with 7 samples.

How the data were processed

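The series holds ribosome profiling and RNA-seq of mouse epidermis, with 7 libraries in the labels: 2 KO and 2 WT ribosome profiling libraries, and 2 KO and 1 WT RNA-seq libraries. Per the labels, total RNA was depleted of ribosomal RNA with a RiboZero-Gold kit, and growth, extraction and library protocols are given only as citations. The submitters' processing notes name CASAVA 1.8, Bowtie2 2.2.6, TopHat2 2.0.10 and the builds hg19 and mm9, without a role or an order. Which tool aligned which library, how reads that match several genes were treated, and how footprints were assigned to a position are not given in the sources used here. Each of these can change counts of gene families and of short regions.

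The deposited tables give raw counts of footprints for 13167 transcripts, 1 UCSC transcript per gene as a rule, in the whole transcript, the 5′ UTR, the coding region and the 3′ UTR, per the file headers. Of the transcripts, 4 carry no symbol and 223 share a symbol with another, leaving 13047 distinct symbols. The deposited count columns used here are those of the 4 ribosome profiling libraries; RNA-seq counts were not used here. Ratios that the authors deposited beside the counts were not used. The file headers describe 1 table as full-length footprints of 28 to 34 nt and the other as short footprints of 20 to 22 nt, but the 2 tables are byte-identical. The length class of the counts is therefore unknown, and short and full-length footprints were not compared. The 3 regions leave 71 nt of each transcript uncovered, the same in every transcript; their position is not described.

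A count is listed only where the coding density exceeds 0.01 footprints per nt, found from the values: 0 listed values lie at or below it. An unlisted value is an upper bound, not a 0, so the test used the 11019 transcripts listed in all 4 libraries. Transcripts listed in both libraries of 1 genotype and in neither of the other were given a lower bound of the change, from the largest count an unlisted value can have. Filtering on at least 10 counts in at least 2 libraries left 10953.

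Libraries were grouped by the genotype in their titles. The planned model covered 7 libraries and both assays; since RNA counts were not used, the same model was fitted to the 4 ribosome profiling libraries. Coding counts were scaled with TMM factors (0.928 and 0.959 in KO, 1.09 and 1.03 in WT) and tested with edgeR 4.0.16 (quasi-likelihood test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are these counts normalised to library size, and the biological coefficient of variation was 11.1%. The ratio of 3′ UTR to coding counts was tested as the interaction of genotype and region with the library as a factor, with TMM within each region, for 223 genes with at least 10 counts in at least 2 libraries in each region. TMM within a region sets the typical change of the ratio to about 0, so these calls are relative to it. Summed ratios were compared by two-sided exact permutation tests, whose smallest p for 2 against 2 libraries is 0.33.

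Before the data were examined, 28 gene lists with 914 symbols, the tests, most alternatives and the rule for named genes were fixed; 847 symbols were in the table and 27 lists could be tested, as no mitochondrially encoded gene was listed. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 27 lists. Of the 27 lists, 19 passed the threshold with the preset correlation, and none of these 19 passed with a correlation estimated from the data. The rule named Pelo, the 12 largest rises and the 12 largest falls among genes past the threshold whose genotypes did not overlap, without predicted genes and those with a mean under 20 counts, and up to 4 members of each list with the largest change. It named 123 genes, all past the threshold. A marker set of 10 cell types was fixed too; other genes were named after their values were seen. A few genes that the rule or a count would name are not reported here.

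Depth limits precision: a median of 90 to 112 coding footprints per listed transcript gives good precision for abundant genes, while 3′ UTR counts were mostly near the filter. Counting intervals cover counting error only, as reads without molecular identifiers are not independent molecules. On counts simulated for the coding comparison with 10933 genes, the test called 14.7% of genes changed by log2 0.5, 83.3% of those changed by 1 and all of those changed by 2, with 2.96% of calls on unchanged genes. In the simulated 3′ UTR comparison with 190 genes, 92.9% of genes changed by log2 2 were called, with 1.89% of calls on unchanged genes. The coding simulation changed only 200 genes, against 4277 called in the data, and set the spread of each gene by its abundance alone. The 3′ UTR simulation changed 56 of its genes and gave every gene the same fixed spread. These rates hold for those settings and need not hold for the data. Alternatives were RLE size factors, no filter, a replicate block, each library left out in turn, DESeq2 1.42.0, and other list tests and 3′ UTR scalings. Added after seeing the data were library totals without TMM, unlisted counts set to 0 or to their upper bound, and the test without genes of lists for other cell types. Tables and tests outside R used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots matplotlib 3.10.9. No reference genome of the build was used, so coordinates are not given.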

Results

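Ribosome profiling sequences the piece of mRNA that a ribosome covers, so footprint counts over a coding region measure how many ribosomes were on it. The series set out to compare primary epidermis, the outer layer of the skin, of wild-type (WT) mice with that of mice carrying a transgenic knockout (KO) of Pelo. Pelo encodes Pelota, which is known to act with the GTPase Hbs1l in releasing ribosomes that have stalled on mRNA. Footprint counts per transcript region came from 2 KO and 2 WT libraries. The labels also list 2 KO and 1 WT RNA-seq libraries, which were not analysed here, so a change in footprints below can come from more mRNA or from more ribosomes per mRNA. It can also come from a different mix of cells: although the series names epidermis, dermal fibroblast genes held 5.09% and 5.70% of coding footprints in KO and 9.83% and 14.3% in WT, and adipocyte and muscle genes were present too. Coding footprints numbered 4925876 and 4521561 in KO replicates 1 and 2, and 5282276 and 4221675 in WT replicates 1 and 2, with a median of 90 to 112 per listed transcript. Log counts correlated across genes at r = 0.983 between replicates of either genotype and at 0.898 to 0.907 between genotypes; genes are not independent replicates. Replicates differed by more than sampling noise, with a chi-square per gene of 5.50 for KO and 10.1 for WT. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these samples.

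Pelo itself carried fewer footprints in both knockout libraries. Its coding region of 1098 nt (transcript uc007ryb.2) held 24 and 21 footprints in KO against 101 and 61 in WT, or 5.05 ± 0.290 against 15.8 ± 2.59 CPM (normalised counts scaled to a common library size; mean ± SD, n = 2 per genotype). That is 3.14-fold lower in KO (log2 change −1.65, SE 0.245, adjusted p = 0.000807). Footprints remained in both KO libraries; the labels do not say which part of the gene was deleted or in which cells.

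Footprints on Krt1, on cornified envelope genes and on hair protein genes rose in the knockout, while those on most sebaceous gland genes, on type I collagen and on several T cell genes fell. Of 10953 genes tested, 2184 were higher and 2093 lower in KO at an adjusted p of 0.05, together 39.0% of the genes. Among them, 797 rose and 719 fell by over 2-fold. Among genes listed in all 4 libraries, the largest rises were in keratin-associated proteins, which form the matrix of the hair shaft: Krtap8-1 (log2 change 6.33, SE 0.606), Krtap7-1 (5.94, SE 0.292), Krtap16-1 (5.74, SE 0.571), Krtap6-5 (5.49, SE 0.315) and Krtap6-1 (5.31, SE 0.428). With them rose the cysteine protease inhibitors Stfa1 (5.84, SE 0.351) and Stfa3 (5.49) and their relatives BC100530 (5.71) and BC117090 (5.62), the hair and epidermal proteins Tchh (trichohyalin, 5.46) and Prr9 (5.49), and Sprr1b (5.37), a cross-linked cornified envelope protein. The largest falls among these genes were in the serine protease inhibitor family members Serpinb6e (−5.11, SE 0.187) and Serpina3b (−5.02, SE 0.382) and in the cytochromes P450 Cyp2g1 (−4.91, SE 0.360) and Cyp2f2 (−3.32). Retnla, a secreted product of alternatively activated macrophages, fell by 3.66 on the log2 scale, the guidance factor Sema3e by 3.30, the channel Panx3 by 3.27, the growth factor binding protein Igfbp6 by 3.20 and the collagen-binding proteoglycan Fmod by 3.02. Mrgprb3 (−3.43), Scg3 (−3.05) and the ribonuclease Ear11 (−3.02) complete the 12 largest. Several of these, among them the Krtap, Stfa and Ear genes, have near-identical copies between which reads may have been shared, so their separate values are uncertain. Leaving out 1 library moved several folds by over 1.5 times: log2 changes ran from 4.29 to 7.59 for Krtap6-1, 4.84 to 6.31 for Krtap16-1, 5.26 to 6.68 for Stfa1, 4.89 to 6.33 for Stfa3, 5.15 to 6.52 for BC100530, 5.01 to 6.53 for BC117090, 4.98 to 6.10 for Tchh, 4.78 to 6.22 for Sprr1b, −6.12 to −4.38 for Serpina3b, −5.95 to −4.28 for Cyp2g1, −4.75 to −3.06 for Retnla and −3.91 to −2.48 for Ear11. Krtap6-5 ran from 4.82 to 6.36 when 1 WT library was left out; with 1 KO library left out, it, Krtap7-1, Krtap8-1 and Prr9 missed the count filter and were not tested.

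Both KO libraries lay on the same side of both WT libraries for 7878 genes, 71.9% against 33.3% by chance, and this held for all 4277 called genes. Scaled to library totals alone, a choice made after seeing the data, the split was 1523 higher and 2986 lower. That scaling moved the median of all genes by −0.17 (log2), and the changes given here are relative to the default TMM scaling. DESeq2 called 1492 genes higher and 1177 lower.

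**Figure D1:**
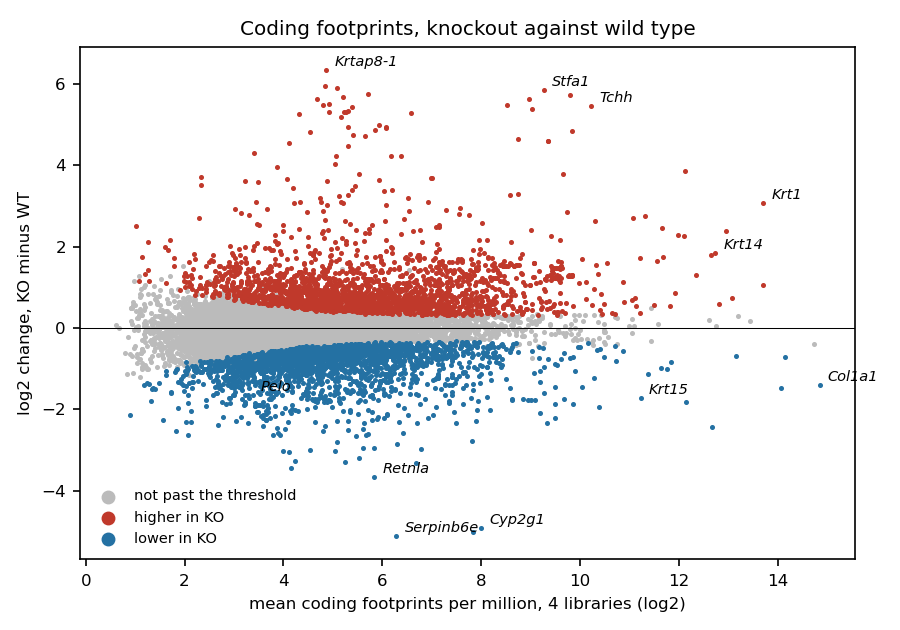
Each point is 1 of the 10953 tested genes, with its mean TMM-normalised coding footprints over the 4 libraries (log2 CPM) on the horizontal axis and its log2 change, KO minus WT, on the vertical axis. Red and blue points passed the adjusted p of 0.05 as higher (2184) or lower (2093) in KO; labels mark genes named in the text, such as Krt1, Stfa1 and Pelo.

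Among keratinocyte genes, suprabasal and stress genes carried more footprints in KO, while basal genes went both ways. Krt1, the type II keratin of the suprabasal layers, held 23950 ± 2209 CPM in KO against 2862 ± 394 in WT (log2 change 3.06, SE 0.191, adjusted p = 8.81e-06), and its partner Krt10 rose by 1.06. Flg, the precursor of the keratin-bundling protein filaggrin, held 8404 ± 772 CPM against 578 ± 1.79 (3.86, adjusted p = 3e-06), and Casp14, a protease involved in filaggrin processing, rose by 3.11. Of 19 tested members of the wound and stress list, 18 rose and the cytokine Il1b (1.22, adjusted p = 0.0637) did not pass the test. The median log2 change was 2.92 (camera adjusted p = 8.4e-39; adjusted p = 0.21 with an estimated correlation), and all 19 rose adjusted over the list alone. A further 7 members were listed in both KO libraries and in neither WT library. Il1f6 had 182 and 146 footprints in KO, where an unlisted value can reach 4. Others were near the listing limit: Sprr2k had 3 and 2, where an unlisted value can reach 1, and Tslp 5 and 10, where it can reach 3. The count of 7 therefore does not show 7 large rises. Of 36 cornified envelope genes, 31 rose, among them Tchh, Lce3f (4.94), Ivl (2.27) and Tgm1 (1.68), 1 fell and 4 were not called. Adjusted over the list alone, 32 rose and 1 fell, with a median of 1.43 (camera adjusted p = 1.1e-32; adjusted p = 0.21 with an estimated correlation). The exception was Lce1m, a late cornified envelope protein (−1.86, adjusted p = 2.27e-05). Lipk (0.47), Lipm (0.12), Tgm5 (−0.20) and Flg2 (−0.11) were the 4 not called; list members named as exceptions, here and in the other lists, were chosen after their values were seen. In the spinous list 8 of 15 rose, including the calcium-binding Calm4 (2.70) and the desmosomal cadherin Dsc1 (1.55), 6 were not called and Skint5 fell (−0.90). The median was 0.59 (camera adjusted p = 3.7e-05; adjusted p = 0.48 with an estimated correlation), and 9 rose and 1 fell adjusted over the list alone.

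Among 16 basal keratinocyte genes, 6 rose, 4 fell and 6 were not called, the same numbers as when adjusted over the list alone. Krt14, the main basal type I keratin, rose by 1.84 (10670 ± 788 against 2976 ± 452 CPM) and the hyaluronan receptor Cd44 by 1.06. Krt15, a keratin of basal and hair follicle stem cells, fell by 1.72 on the log2 scale (1118 ± 203 against 3682 ± 7.21 CPM), and the other falls were the caveola protein Cav1 (−0.64), the hemidesmosome proteins Dst (−0.59) and Col17a1 (−0.47). The basal transcription factor Trp63 (0.10, adjusted p = 0.503) and the integrin Itga6 (−0.08) did not pass. The list median was 0.10, or −0.07 with library totals alone (camera adjusted p = 0.34). The dermal fibroblast list held 5.09% and 5.70% of coding footprints in KO against 9.83% and 14.3% in WT. Genes of the cornified list took 4.81% and 4.41% against 1.63% and 1.5%. Without KO replicate 1, Col17a1 (−0.48) lost its call, Il1b gained one (1.75), Skint5 stood at −1.38 and Lipk at 0.26; without KO replicate 2, Col17a1 (−0.45) also lost its call, Skint5 stood at −0.53 and Il1b at 0.44, and Lipk passed (0.66). Without WT replicate 1, Skint5 (−0.78) lost its call and Il1b stood at 0.66, and without WT replicate 2, Il1b passed (1.94). Lce3f ran from 4.38 to 5.62 when 1 library was left out. Skint5 also missed with unlisted counts at 0 (−0.90), and Tgm5 passed with library totals (−0.37).

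**Figure D2:**
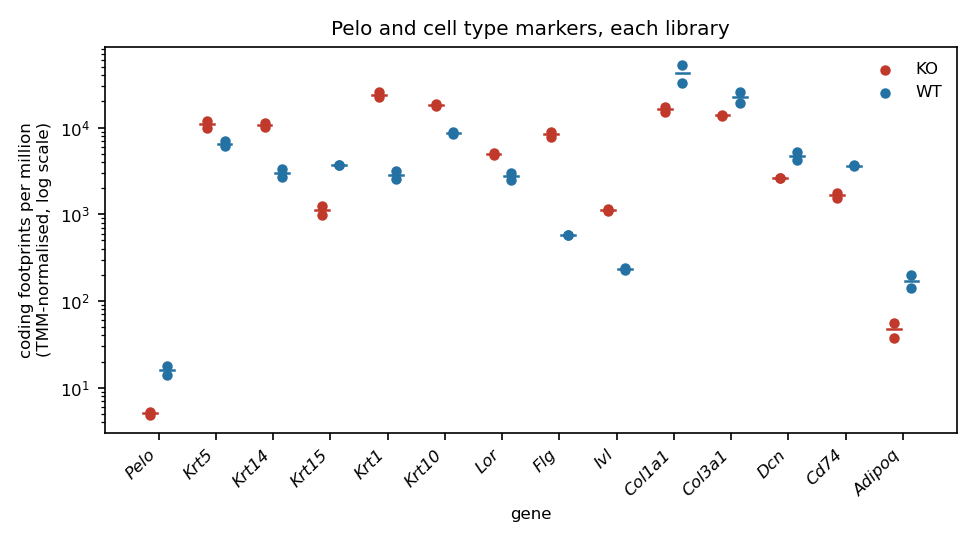
TMM-normalised coding footprints (CPM, log axis) for Pelo and 13 genes picked from the larger marker set that was fixed beforehand. Each point is 1 library and each short line the mean of a genotype, KO in red and WT in blue. The 13 all passed the threshold, and markers that did not, such as Itga6, Trp63, Sbsn, Lum, Cd207, Acta1 and Pecam1, are not shown. Krt1, Flg and Ivl are higher in both KO libraries, and Krt15, Col1a1, Cd74 and Adipoq are higher in both WT libraries.

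Hair shaft and root sheath genes rose in 14 of 18 tested members, with 3 not called, and melanocyte pigment genes rose with them. Krt86, a hair keratin whose reads may be shared with Krt81, held 239 ± 134 CPM in KO against 18.4 ± 0.413 in WT (log2 change 3.70, SE 0.355, adjusted p = 5.87e-05). Gata3, a transcription factor of the inner root sheath and of lymphocytes, fell (−1.34), and Krt72 (0.83), Krt75 (0.23) and Trps1 (−0.15) were the 3 not called. The median was 2.16 (camera adjusted p = 1.8e-09; adjusted p = 0.30 with an estimated correlation), and 14 rose and 1 fell adjusted over the list alone. Another 5 hair members were listed in both KO libraries and in neither WT library, among them Krt28 with 514 and 96 footprints and Padi3 with 205 and 35. Krt84, with 36 and 21, was near the listing limit, as an unlisted value can reach 17. Replicates differed widely here: Krt86 had 1525 footprints in KO replicate 1 and 626 in KO replicate 2, and its log2 change ran from 2.98 to 4.19 when 1 library was left out. Of 8 melanocyte genes, 5 rose: Pmel (3.78), Mlana (3.52), Dct (3.26) and Tyrp1 (3.26), which act in pigment synthesis and melanosomes, and the receptor Kit (1.32). The lineage transcription factors Mitf (−1.03, adjusted p = 0.0133) and Sox10 (−0.82, adjusted p = 0.00706) fell, and Gpnmb (0.28) was not called. Pmel had 555 and 219 footprints in KO and ran from 3.02 to 4.29 when 1 library was left out; Mlana had 59 and 25 in KO and was not tested without either KO library. The numbers were the same adjusted over the list alone, with a median of 2.29 (camera adjusted p = 0.0016; adjusted p = 0.45 with an estimated correlation).

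In the hair follicle stem cell list 6 of 14 members fell: the matricellular protein Ctgf (−1.90), the stem cell marker Cd34 (−1.36), the receptors Lgr6 (−1.34) and Lgr5 (−0.64), and the transcriptional regulators Nfatc1 (−1.16) and Id2 (−0.64). Plet1, a marker of the upper follicle and its infundibulum, rose by 1.65 and the matrix protein Postn by 1.32, and 6 were not called. Adjusted over the list alone, 2 rose and 7 fell, with a median of −0.39 (camera adjusted p = 0.22). The stem cell genes Fgf18 and Lhx2 were listed in both WT libraries and in neither KO library, a fall of at least 4.99-fold and 4.27-fold. Sebaceous gland genes fell in 13 of 18 members. The P450 Cyp2g1 fell by 4.91, the fatty acid elongase Elovl5 by 2.33, the fatty acyl reductase Far2 by 2.29 and the wax synthase Awat2 by 2.26, all on the log2 scale. Without 1 library, Cyp2g1 ran from −5.95 to −4.28, Far2, with 176 and 540 footprints in KO, from −3.36 to −1.67, and Awat2, with 11 and 27, from −3.07 to −1.71. Prdm1, a transcription factor of gland progenitors and of differentiating keratinocytes, rose by 1.60. Fads2 (0.70), Elovl3 (−0.53), Dgat2 (−0.24) and Fasn (−0.24), lipid enzymes active in other cells too, were not called. The counts were the same adjusted over the list alone, with a median of −1.39 (camera adjusted p = 4.9e-08; adjusted p = 0.35 with an estimated correlation). Fibroblast genes, at 5.09% and 5.70% of coding footprints in KO and 9.83% and 14.3% in WT, moved in the same direction as the sebaceous genes. With library totals Fasn passed (−0.41). With DESeq2, Lgr5 (−0.63) and Id2 (−0.62) did not pass, nor did Id2 with unlisted counts at 0 (−0.64). Without KO replicate 1, Id2 (−0.47) lost its call, and Krt72 stood at 0.01, Krt75 at −0.06, Gpnmb at −0.07, Fads2 at 0.14 and Elovl3 at −0.07; without KO replicate 2, Krt72 (1.36), Krt75 (0.48), Gpnmb (0.57), Fads2 (1.11) and Elovl3 (−1.15) passed. Without WT replicate 1, Id2 (−0.40) lost its call, Krt72 (1.46) passed, Krt75 stood at 0.12, Fads2 at 1.40 and Dgat2 at 0.05, and without WT replicate 2, Mitf (−0.64) lost its call, Dgat2 (−0.49) passed, Krt72 stood at 0.41 and Fads2 at 0.30.

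Genes of the translation machinery rose together. All 78 tested cytosolic ribosomal protein genes were higher in KO, by log2 changes of 1.09 to 2.50, and they took 2.13% and 2.21% of coding footprints in KO against 0.925% and 0.874% in WT. Rpl23a, a large subunit protein, held 54.2 ± 13.4 CPM against 12.3 ± 3.12 (log2 change 2.12, SE 0.225, adjusted p = 0.000107), and Rps2, of the small subunit, 20.6 ± 6.70 against 5.38 ± 1.45 (1.97, adjusted p = 0.000941). All 78 also rose adjusted over the list alone; the median was 1.45 (camera adjusted p = 8.8e-63; adjusted p = 0.053 with an estimated correlation). Many ribosomal protein genes have processed pseudogenes, and how the authors' counting treated shared reads is not given in the sources used here. Of 48 translation factors, 41 rose, including Tpt1 (1.72), the elongation factor subunits Eef1g (1.55) and Eef1b2 (1.45), and the initiation factor Eif1a (1.36). The RNA helicase Eif4a2 fell (−0.80) and 6 were not called. The median was 0.75 (camera adjusted p = 6.6e-13; adjusted p = 0.21 with an estimated correlation), and 41 rose and 1 fell adjusted over the list alone. The mix of cells differed as well, with cornified genes at 4.81% and 4.41% of coding footprints in KO against 1.63% and 1.5% in WT and fibroblast genes lower in share, and how much of these rises it accounts for was not tested.

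In the ribosome rescue and mRNA decay list, which covers Pelota's known role, 17 of 55 members rose, 37 were not called, and the nonsense-mediated decay factor Smg6 fell (−0.47). The largest rises were in Gnb2l1, which encodes the 40S-bound scaffold Rack1 (1.55, adjusted p = 4.13e-05), the cap-binding protein Eif4e2 (1.22), the recycling factor Mcts1 (0.99) and Abce1, the ATPase that splits ribosomal subunits (0.97). Hbs1l, Pelota's partner, had 31.7 CPM in KO against 24.4 in WT and did not pass (0.39, SE 0.174, adjusted p = 0.108). The median was 0.24 (camera adjusted p = 0.027; adjusted p = 0.30 with an estimated correlation), and 15 rose and 1 fell adjusted over the list alone. Nuclear genes of oxidative phosphorylation rose in 52 of 75, with 23 not called; Cox5a (0.95), Ndufa4 (0.95), Ndufa12 (0.95) and Cox5b (0.94) led. Adjusted over the list alone, 55 rose, with a median of 0.52 (camera adjusted p = 2.9e-07; adjusted p = 0.36 with an estimated correlation). Heat shock and proteasome genes rose in 34 of 43, with 9 not called, led by the proteasome subunits Psmc4 (0.90), Psmd12 (0.78) and Psmb5 (0.75) and the chaperonin Hspe1 (0.88). The median was 0.53 (camera adjusted p = 7.1e-06; adjusted p = 0.32 with an estimated correlation), and 36 rose and 1 fell adjusted over the list alone. Without WT replicate 1, the rescue list missed the threshold (camera adjusted p = 0.060) and Smg6 (−0.45) lost its call, as it did without KO replicate 2 (−0.33) and WT replicate 2 (−0.49) and with DESeq2 (−0.45). Hbs1l passed without WT replicate 2 (0.58).

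Cell cycle genes and histones were higher in KO, as were the shares of keratinocyte lists, while adipocyte genes took 0.106% and 0.0828% of coding footprints in KO against 0.263% and 0.195% in WT and immune cell genes 0.488% and 0.525% against 0.960% and 1%; a different mix of cells was not tested as the cause. Of 34 proliferation genes, 32 rose, among them the mitotic regulators Ube2c (1.82), Cdc20 (1.62, SE 0.136, adjusted p = 2.99e-05), Birc5 (1.66) and Ccnb1 (1.57). The replication helicase subunit Mcm6 (0.38) and the transcription factor E2f1 (0.01) were not called. The median was 1.2 (camera adjusted p = 7.3e-16; adjusted p = 0.30 with an estimated correlation), and 33 rose adjusted over the list alone. All 55 tested histone genes rose, also adjusted over the list alone, with a median of 1.29 (camera adjusted p = 3e-48; adjusted p = 0.30 with an estimated correlation). Hist1h2ab rose by 1.64 and Hist2h3c2 by 1.61; many histone genes share near-identical coding regions, so that the 55 are not separate observations. In the p53 target list 9 of 25 rose, 4 fell and 12 were not called, also adjusted over the list alone. The risers included the apoptosis gene Pmaip1 (1.72) but also Psrc1 (1.59) and Ckap2 (1.53), which encode spindle proteins. The 4 that fell were the ribonucleotide reductase subunit Rrm2b (−1.58), Sesn1 (−0.90), the death receptor Fas (−0.76) and the p53 ligase Mdm2 (−0.55). The list median was 0.21 (camera adjusted p = 0.18). Immediate early genes rose in 10 of 19, with 8 not called and Klf6 lower (−0.48). Egr2, a growth factor induced transcription factor, rose by 1.72 (adjusted p = 0.000222), and Ier3 by 1.57. Adjusted over the list alone, 11 rose and 1 fell, with a median of 0.80 (camera adjusted p = 0.017; adjusted p = 0.65 with an estimated correlation). This list rested on KO replicate 2: without it the camera adjusted p was 0.32, and Fos, with 178 and 815 footprints in KO against 219 and 153 in WT (1.62), stood at 0.10 and Junb (1.06) at 0.66. Klf6 lost its call without KO replicate 1 (−0.32) or WT replicate 2 (−0.41), and Fas (−0.70 to −0.81) without any 1 library. Mdm2 lost its call without KO replicate 1 (−0.43), WT replicate 1 (−0.61) or WT replicate 2 (−0.51), Fos also without WT replicate 1 (1.69) or WT replicate 2 (1.57), Mcm6 passed without WT replicate 1 (0.63), and Pmaip1 was not tested without either KO replicate. With DESeq2, Fos (1.64), Klf6 (−0.47), Fas (−0.75) and Mdm2 (−0.54) did not pass, nor did Klf6 with unlisted counts at 0 (−0.48), or Fos with library totals (1.47) or unlisted counts at 0 (1.63) or at their upper bound (1.65).

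Stress response and lipid synthesis lists went both ways. Of 39 ATF4 targets, which serve amino acid supply under stress, 13 rose, 6 fell and 20 were not called, the same numbers adjusted over the list alone. The asparagine synthetase Asns (1.22, SE 0.144), the arginine transporter Slc7a1 (1.14) and the transcription factor Cebpb (1.11) rose, while the proline synthesis enzyme Pycr1 fell (−1.33). The list median was 0.30 (camera adjusted p = 0.09). In the unfolded protein response list 2 of 23 rose, the translocon subunit Sec61b (0.83, adjusted p = 0.00462) and the chaperone Hyou1 (0.38), and 2 fell, Herpud1 (−0.54) and Sel1l (−0.39), which both act in disposal of misfolded proteins, and 19 were not called. Adjusted over the list alone, 1 rose and 1 fell; the median was 0.07, or −0.10 with library totals alone (camera adjusted p = 0.55). Cholesterol synthesis and mTORC1 genes rose in 10 of 25 members, led by the isomerases Idi1 (1.23, adjusted p = 4.53e-05) and Ebp (0.91) and the sterol enzymes Sc5d (0.91) and Cyp51 (0.88). A further 2 fell, among them the lipogenic transcription factor Srebf1 (−0.51), and 13 were not called. The median was 0.30 (camera adjusted p = 0.030; adjusted p = 0.59 with an estimated correlation), and 10 rose and 3 fell adjusted over the list alone. Interferon response genes fell in 14 of 37, with 21 not called. Usp18, a protease that removes Isg15, fell by 2.05 on the log2 scale (4.37 ± 0.315 against 18.2 ± 1.15 CPM), while the antiviral synthetases Oas1a (1.41) and Oas1g (1.34), close paralogs, rose. The median was −0.44 (camera adjusted p = 0.012; adjusted p = 0.66 with an estimated correlation), and 3 rose and 15 fell adjusted over the list alone. Without KO replicate 1, the interferon list (camera adjusted p = 0.14) and the cholesterol list (0.10) lost their calls, and without KO replicate 2, Herpud1 (−0.41), Sel1l (−0.32), Hyou1 (0.36), Srebf1 (−0.40), Oas1a (0.74) and Oas1g (0.55) did. Without WT replicate 1, the interferon list (0.38), Srebf1 (−0.37), Hyou1 (0.38), Oas1a (1.28) and Oas1g (1.16) lost theirs, and without WT replicate 2, the cholesterol list (0.13), Sel1l (−0.31), Hyou1 (0.36) and Oas1g (1.49). Calls also ended with DESeq2 for Sel1l (−0.38) and Hyou1 (0.39), with library totals for Hyou1 (0.21) and Oas1g (1.17), and with unlisted counts at 0 for Sel1l (−0.39), Oas1a (1.42) and Oas1g (1.34).

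Most adipocyte genes and some fibroblast and immune cell genes were lower in KO. Col1a1, a chain of type I collagen, held 16190 ± 1698 CPM in KO against 42910 ± 14830 in WT (log2 change −1.41, SE 0.255, adjusted p = 0.00241), and Col1a2 fell likewise (−1.47). The matrix proteins Ogn (−1.41), Sparc (−0.98), Dcn (−0.85) and Col3a1 (−0.70) also fell. Of 24 fibroblast genes, 11 fell, 12 were not called, among them Lum (−0.39, adjusted p = 0.10), and the collagen VI chain Col6a3 rose (0.64, adjusted p = 0.00531). Adjusted over the list alone, 1 rose and 12 fell, with a median of −0.40 (camera adjusted p = 0.0099; adjusted p = 0.64 with an estimated correlation). Adipocyte genes fell in 10 of 11, also adjusted over the list alone, with Lpl not called (−0.17). They included Adipoq (adiponectin, −1.86), the lipid droplet protein Plin4 (−1.66) and Cfd (adipsin, −1.47); the median was −1.26 (camera adjusted p = 3.7e-05; adjusted p = 0.39 with an estimated correlation). Immune cell genes fell in 14 of 26, with 11 not called. T cells had no list of their own; the T and natural killer cell genes Cd7 (−2.62), Cd3e (−2.57), Cd3g (−2.48) and Nkg7 (−1.91) fell most, and the antigen presentation chaperone Cd74 fell by 1.14 (1653 ± 169 against 3649 ± 13.8 CPM). Langerhans cell langerin, Cd207, did not pass (−0.45, adjusted p = 0.0521), and Epcam, an adhesion molecule of Langerhans cells and of epithelial cells, rose (0.78). The median was −0.55 (camera adjusted p = 5.5e-05; adjusted p = 0.30 with an estimated correlation), and 1 rose and 15 fell adjusted over the list alone. Without KO replicate 1 or 2 Col3a1 missed the threshold (−0.67 and −0.71), and without WT replicate 2 it stood at −0.46 and the fibroblast list lost its call (camera adjusted p = 0.066). Lum passed without WT replicate 1 (−0.64), and Cd207 without WT replicate 2 (−0.61); with library totals Lum (−0.55), Cd207 (−0.62) and Lpl (−0.33) passed.

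Skeletal muscle, endothelial and erythroid lists did not pass the list test. Of 4 tested muscle genes 3 fell, also adjusted over the list alone: the intermediate filament Des (−2.13, adjusted p = 0.000425), the light chain Mylpf (−2.37) and Tpm2 (−0.46), while Acta1 did not pass (0.10). The list median was −1.30 (camera adjusted p = 0.097). Myosin Myh4 had 2562 footprints in WT replicate 1, 291 in WT replicate 2 and 63 in KO replicate 1, and the list took 0.271% of coding footprints in WT replicate 1, 0.0862% in WT replicate 2, and 0.0565% and 0.0624% in KO. In the endothelial list Flt1 rose (0.99), the tight junction protein Cldn5 fell (−0.75) and 8 of 10 were not called, also adjusted over the list alone; the median was −0.27 (camera adjusted p = 0.48). The globins Hbb-bt (0.88) and Hbb-bs (0.85), which are near-identical, and the erythrocyte enzyme Bpgm (0.81) rose while Hba-a2 did not pass (0.10); 3 of 4 rose adjusted over the list alone, with a median of 0.83 (camera adjusted p = 0.22). Without KO replicate 1, the muscle list passed and Cldn5 (−0.61) and Tpm2 (−0.31) lost their calls, and without KO replicate 2 the list passed and Bpgm (0.64) lost its call. The muscle list then held other genes: those unlisted only in the library left out could enter. Among them were Myh4, Ckm and Atp2a1 without KO replicate 2, and Eno3 without KO replicate 1. Des ran from −2.80 to −1.65 when 1 library was left out. Without WT replicate 1, Mylpf (−0.59), Cldn5 (−0.58), Hbb-bt (0.44), Hbb-bs (0.40) and Bpgm (0.69) lost their calls. Without WT replicate 2 the muscle and erythroid lists passed, the globins stood at 1.43 and 1.44, and Tpm2 (−0.39) and Bpgm (0.91) lost their calls. Mylpf (−2.31), Cldn5 (−0.73), Tpm2 (−0.45) and Bpgm (0.82) did not pass with DESeq2, nor did Hbb-bs (0.69) and Bpgm (0.64) with library totals, Hbb-bt (0.88), Hbb-bs (0.85), Bpgm (0.81), Mylpf (−2.33) and Tpm2 (−0.46) with unlisted counts at 0, or Mylpf at their upper bound (−2.35).

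**Figure D3:**
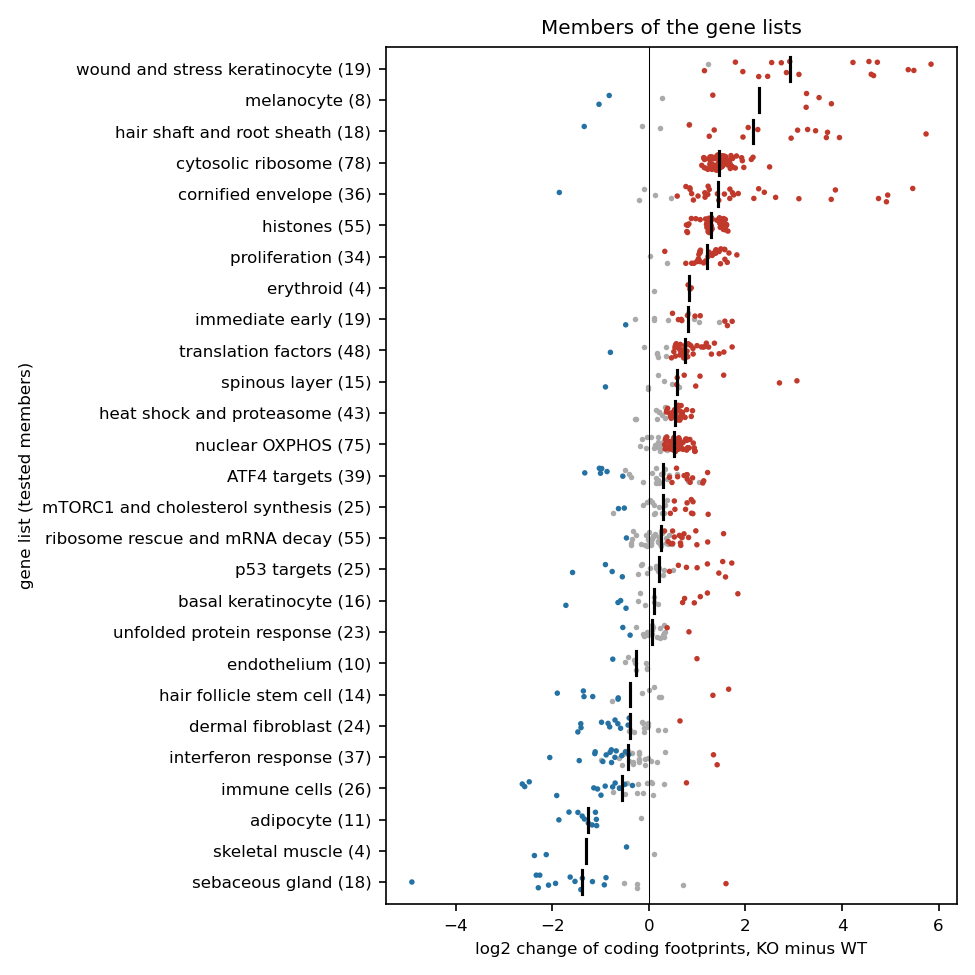
Log2 change of coding footprints, KO minus WT, for every tested member of the 27 gene lists, with the number tested in parentheses; red and blue points rose or fell at an adjusted p of 0.05, grey points did not pass, and black bars are list medians. All 78 ribosomal protein genes and all 55 histone genes lie above 0, while basal keratinocyte genes lie on both sides.

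Some transcripts were listed in the libraries of only 1 genotype. A value is listed only above a density of 0.01 footprints per nt, so these transcripts cannot enter the test, but the threshold gives a lower bound of their change. In both KO libraries and neither WT library stood 187 transcripts, of which 112 were at least 2-fold and 64 at least 4-fold higher. They included Krtap15, a hair matrix protein (at least 50-fold higher), the epidermal interleukin Il1f6 (at least 36.8-fold), the trichohyalin relative Tchhl1 (at least 16.5-fold), the cell cycle inhibitor gene Cdkn2a (at least 13.3-fold) and the cornified envelope gene Crnn (at least 11.8-fold). In both WT libraries and neither KO library stood 548 transcripts, of which 87 were at least 2-fold and 32 at least 4-fold lower in KO. Hamp2 and Hamp, which encode hepcidins, were at least 46.2-fold and 22.7-fold lower, the peptide hormone gene Cck at least 14-fold and the homeobox gene Hoxa7 at least 12.5-fold. These genes were chosen after their values were seen.

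Because Pelota acts on ribosomes that have run past or stalled near the end of a message, 3′ untranslated region (3′ UTR) footprints were set against coding footprints of the same gene and library. Dusp1, an immediate early phosphatase, had the smallest p: its 3′ UTR held 26 and 42 footprints in KO against 147 and 206 in WT, or 6.27% and 6.5% of its coding footprints against 34.9% and 73.6% (log2 change of the ratio −2.51, SE 0.402, adjusted p = 2.36e-07). The ratios of the peptidyl-tRNA hydrolase family gene Ptrhd1 (−1.31) and the desmosomal plakophilin Pkp1 (−1.29) also fell. Ptrhd1 rested on few coding footprints, 26 and 31 in KO against 13 and 8 in WT. Its 3′ UTR footprints overlapped between genotypes, with 32 and 29 against 53 and 25. Ratios rose for the protease inhibitor Cst6 (2.31), the stress keratin Krt17 (2.05), the basal keratin Krt5 (1.65) and the elongation factor Eef1a1 (1.25). Klk6, an epidermal protease, had 71 and 37 such footprints in KO and 0 in either WT library, on 268 and 338 coding footprints in WT. In all, 57 of 223 tested genes passed, 29 with a higher and 28 with a lower ratio in KO. Both libraries of 1 genotype held under 10 such footprints for 13 of the 29 and 22 of the 28, and median coding counts were 7612 for the former and 208 for the latter group. Over all genes together the ratio was lower in KO: 0.591% ± 0.050 of coding footprints against 0.669% ± 0.021, in a two-sided exact permutation test with p = 0.33, the smallest that 2 against 2 libraries allow. A single gene, Lrrc58, held 49.5% and 49.1% of all 3′ UTR footprints in KO and 44.3% and 39.3% in WT; without it the ratio was 0.3% ± 0.027 against 0.389% ± 0.012. The per-gene calls depend on the scaling: with library totals in place of TMM within each region, edgeR called 0 genes (75 at an unadjusted p under 0.05) and Dusp1 stood at −2.99 (adjusted p = 0.058). Without KO replicate 1 the count was 7, without KO replicate 2 it was 35, without WT replicate 1 it was 11 and without WT replicate 2 it was 5; Dusp1 passed in each, with log2 changes from −3.37 to −2.40. Calls were lost without KO replicate 1 by Krt5 (1.25), Eef1a1 (0.95) and Pkp1 (−0.91), without KO replicate 2 by Ptrhd1 (−0.98), without WT replicate 1 by Cst6 (1.09), Eef1a1 (0.72), Ptrhd1 (−1.36) and Klk6, and without WT replicate 2 by Krt17 (1.04), Krt5 (1.17), Eef1a1 (0.85), Ptrhd1 (−2.04), Pkp1 (−1.47) and Klk6. Cst6, Krt17 and Klk6 were not tested without either KO replicate. With no count filter Dusp1 (−2.82) and Pkp1 (−1.60) kept their calls. Cst6 (1.99), Krt17 (1.73), Krt5 (1.32), Eef1a1 (0.93), Ptrhd1 (−1.61) and Klk6 lost theirs.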

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

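In this part, the tests of gene mix, of RNA fragments and of library handling were chosen after the result was seen, and the gene lists were added to that of RNA fragments after their values were seen; those of dermal tissue and of a few genes were not. Footprints outside the coding and 3′ untranslated regions, which the comparisons above do not use, were higher relative to coding footprints in KO than in WT. In the 5′ UTR they came to 1.597% ± 0.174 of coding footprints in KO (1.474% and 1.720%) against 1.041% ± 0.065 in WT (1.088% and 0.995%), or 1.53-fold. In the 71 nt that no region covers they came to 4.651% ± 0.001 (4.651% and 4.652%) against 2.582% ± 0.106 (2.657% and 2.507%), or 1.8-fold. Both KO libraries lay above both WT libraries, and the two-sided exact permutation p was 0.33, the smallest this design allows. With library totals as sizes, edgeR called 480 of 1618 genes higher and 14 lower for the 5′ UTR, and 589 of 2865 higher and 6 lower for the 71 nt; with TMM within each region, which removes a shift shared by all genes, the calls were 10 higher and 17 lower for the 5′ UTR and 12 higher and 21 lower for the 71 nt.

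As the whole explanation of the rise outside the coding regions, the values argue against a different mix of genes. For the 71 nt they also argue against a few genes. With each gene's weight held the same across libraries, the log2 rise was 0.59 for the 71 nt, against 0.85 summed over genes. For the 5′ UTR it was 0.71 against 0.62. A different mix of genes may therefore account for a part of the rise in the 71 nt, but not for the whole. For the 71 nt, the rise was 0.77 without the 20 genes that held the most such footprints, against a few genes as the cause. Within the dermal fibroblast list alone it was 0.67. That value was summed over genes whose changes differed, so the mix of genes within the list may have shifted. Alone it cannot exclude a smaller share of dermal tissue. RNA fragments spread over whole transcripts, which would raise 3′ UTR footprints too, stay open: with fixed weights the 3′ UTR ratio changed by −0.39 (log2), yet it lay higher in both KO than in both WT libraries in 5 of 8 gene lists, such as dermal fibroblast (2.29-fold) and nuclear OXPHOS (1.75-fold), and lower in 1 (immune cells, −0.65). Library handling that differed between genotypes cannot be told apart from the knockout, as the labels give no batch and 2 against 2 libraries cannot go below an exact permutation p of 0.33; both may have contributed, and the position of the 71 nt stays unknown.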

How the results depend on the processing

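Which libraries and genes a call rests on was tested with settings fixed beforehand; library totals without TMM, unlisted counts at 0 or at their upper bound, and the test without genes of other cell types were chosen after seeing the data. The count of 4277 coding calls was 3242 to 4611 under every alternative except DESeq2, and no gene called there and in the reported test changed sign. DESeq2 called 2669 genes, 1177 of them lower, and gave 213 genes no adjusted p; the cause was not tested. Over 219 named genes and 12 alternatives, 2417 of 2571 values kept direction and side of the threshold, 99 lost a call, 28 gained one and 27 reversed. Reversed values belong to genes that had not passed. With library totals they were Trp63 −0.07, Acta1 −0.08, Cry1 −0.13, Clock −0.12, Per1 −0.16, Lipm −0.05, E2f1 −0.15 and Hba-a2 −0.07, after a shift of all genes by −0.17. Leaving out 1 library moved Sbsn from 0.00 to 0.36, Acta1 from −0.18 to 0.43, Cdh5 from −0.21 to 0.08, Cry1 from −0.11 to 0.20, Clock from −0.21 to 0.29, Per1 from −0.32 to 0.30, Lipm from −0.04 to 0.30, Krt75 from −0.06 to 0.48, Trps1 from −0.34 to 0.04, E2f1 from −0.24 to 0.26, Gpnmb from −0.07 to 0.57, Dgat2 from −0.49 to 0.05 and Hba-a2 from −0.01 to 0.22. Where 1 genotype kept 1 library, it was assumed to vary like the others.

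The labels number replicates 1 and 2 in both genotypes but do not say that a number marks a shared animal or batch. Deviations of same-numbered libraries correlated at r = −0.005. With a replicate block the count was 4337, the skeletal muscle list passed (camera adjusted p = 0.048) and E2f1 stood at 0.00. Il1b (1.17), Krt72 (0.80), Fads2 (0.75), Lipk (0.47), Mcm6 (0.40), Lum (−0.37) and Cd207 (−0.44) passed with it and Nfil3 (0.60) did not; it changed no other list's or named gene's call.

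Of the 19 lists past the threshold, 0 held with an estimated correlation. For the cytosolic ribosome list (−0.00032) and the ribosome rescue list (−0.002) the estimate lay below the preset correlation. A larger correlation therefore does not account for the lost calls of these lists, and the cause was not tested. Estimates for the others of the 19 lay above the preset. With fry 11 lists passed, among them the unfolded protein response (adjusted p = 0.0026), which had missed with camera. The fry test asks whether a list moves and not whether it moves more than other genes. The 57 genes with a changed 3′ UTR ratio became 4 without the count filter (2 higher, 2 lower) and 0 with library totals (0 higher, 0 lower; 75 at an unadjusted p under 0.05 in edgeR, no other tool run). Leaving out 1 library gave 5 to 35, with 1 to 16 higher and 2 to 19 lower. The losses without the filter come with more genes, and also with lower log2 values for every gene that the fixed rule named. Cst6 moved from 2.31 to 1.99 and Dusp1 from −2.51 to −2.82. TMM was then taken over more genes, which can move the point that the changes are relative to. The losses with fewer libraries come with fewer samples, and the cause of the others was not tested. Tested genes had a median of 13.0 footprints in the 3′ UTR, which limits these calls.

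Settings fixed beforehand but not run, because RNA-seq and short footprint counts were not used here, were TMM over 7 libraries, the comparison of a fit of 1 assay with a fit of all 7 libraries, everything on RNA counts and on translational efficiency, and everything on short footprints: their ratio tests, their share per library, and that share without the top 20 genes, without mitochondrially encoded genes or on filtered genes.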

Other observations

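All tests and gene families in this part were chosen after the result was seen. Of 12 tested genes of the circadian clock, 6 fell: Tef (−2.63), Nr1d1, a nuclear receptor that represses Arntl (−2.48, 14.8 ± 0.231 against 82.9 ± 1.83 CPM), Cry2 (−1.69), Hlf (−1.29), Nr1d2 (−1.13) and Arntl itself (−0.60). Bhlhe40 (1.34) and Nfil3 (0.61) rose, Clock, Cry1, Per1 and Rora did not pass, and Npas2, Per3, Dbp and Ciart were listed in both WT libraries only. An unlisted KO value can reach 23 footprints for Npas2 (54 and 25 in WT) and 32 for Per3 (61 and 66). It can reach 9 for Dbp (17 and 37) and 10 for Ciart (17 and 23), so these listings need not mean a large fall. Arntl lost its call without WT replicate 2 (−0.49), and Nfil3 without KO replicate 2 (0.46), WT replicate 1 (0.81) or WT replicate 2 (0.45). With DESeq2, Hlf (−1.28), Arntl (−0.59) and Nfil3 (0.63) did not pass, and Nfil3 also missed with library totals (0.43), a replicate block (0.60), unlisted counts at 0 (0.61) or at their upper bound (0.63), and without genes of other cell types (0.60). The labels give no time of day.

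All 8 tested kallikreins, serine proteases of which several act in shedding of the cornified layer, rose, with a median log2 change of 2.55; Klk6 (4.84), Klk14 (3.59), Klk9 (3.20) and Klk7 (2.62) led. Of 6 tested gap junction genes, 3 rose, 1 fell (Gjb5, −0.63) and 2 were not called. Gjb2, the gap junction protein connexin 26, rose most, by 3.38. Tdh, which encodes threonine dehydrogenase, had 983 and 679 footprints in KO against 17 and 30 in WT (5.29, SE 0.293; 4.74 to 5.96 when 1 library was left out). All 7 eosinophil-associated ribonuclease genes, near-identical copies, fell, with a median of −2.59. Of 19 Hox genes in the table, 8 were listed in both WT libraries and in neither KO library, among them Hoxa7 with 99 and 81 footprints and Hoxa5 with 46 and 38. Others were near the listing limit: Hoxd9 had 12 and 14 footprints in WT, where an unlisted value can reach 9, and Hoxc9 12 and 8, where it can reach 7. The count of 8 therefore does not show 8 falls. Of the 4 tested, Hoxc13, which acts in hair differentiation, rose (1.25) and Hoxc6 fell (−1.10).

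A candidate explanation for the rise of all 78 ribosomal protein genes is a trend with coding length, since these genes are short (median coding length 396 nt against 1263 nt for all tested genes). Among 10000 lists of other genes matched on coding length, medians ran from −0.09 to 0.54. The ribosomal median lay above the median of these lists by 1.23. The share of lists with a median as large was taken as 0.0001, the smallest they can give. That share treats genes as independent and does not measure the spread between libraries. The scaling of the libraries does not account for the ribosomal rise either, as the lowest ribosomal median under RLE factors and library totals was 1.28. What stays open is whether mRNA levels or ribosomes per mRNA changed, and the mix of cells and shared reads of pseudogenes, which were not tested; a biological change is a hypothesis only.

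A larger share of all keratinocytes alike in the KO libraries may have raised cornified genes, but it would raise basal genes too. The cornified median lay above the basal median by 1.33 (p = 0.00016 in a permutation of genes between the lists). Genes are not independent replicates, so this p does not measure the spread between libraries. A larger share of cornified cells among the keratinocytes would raise cornified genes without basal ones, and it was not tested. A smaller share of dermal tissue may have lowered fibroblast genes, by about the same amount if no other cells carried them. Their log2 changes spread 3.71 times as widely as their median standard error (SD 0.54 against 0.15), with Col6a3 rising. Other skin cells or kinds of fibroblast may carry list members unequally, so the spread cannot exclude a smaller dermal share as the whole cause. For the cornified rise, the gap between the lists argues against an equal rise of all keratinocytes as the whole cause, though it may be a part. Other changes in the mix of cells stay open, as does a change in gene activity within these cells, which is a hypothesis.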
